A study of Bos taurus with 12 samples.

How the data were processed

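Povidone-iodine was given into the uterus of 3 cows, whose endometrium was sampled by biopsy on 4 days (0, 2, 7 and 14), and total RNA of each biopsy was hybridised to 1 one-colour (cyanine-3) Agilent bovine oligonucleotide array, 12 arrays in all. The labels give the day and the cow of every sample, and the design text says that the same 3 animals were biopsied on all 4 days, which makes the cow a block. The labels do not say which uterine horn a sample came from, what stage of the oestrous cycle the cows were in, or whether the day 0 biopsy was taken before the antiseptic. No untreated cow is among the samples.

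The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 10.5.1.1 per the submitters' processing notes; the difference could not be settled. The processed intensity in them was detrended within each array by that software, per the file headers, and was not scaled between arrays. The authors also deposited a value table on a log2 scale, whose making is not given in the sources used here. Set against the scanner files, each of its columns equals log2 processed intensity minus the array's 75th percentile minus the probe's median over the 12 arrays, with a median absolute difference of at most 0.0007. Scale, centring and direction of the table were found by that comparison alone. The medians of its columns were 0.01 (cow 1), -0.03 (cow 2) and -0.07 (cow 3) on day 0, 0.05, -0.06 and 0.03 on day 2, 0.08, -0.02 and 0.00 on day 7, and -0.03, 0.00 and 0.02 on day 14.

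The scanner files and the value table name different samples for 10 of the 12 arrays. Every table column matched 1 scanner file with a correlation of 1.0 over all probes (the next best file reached at most 0.52), but only 2 of these were the files linked to the same sample. Read by the table, each of the 3 slides holds the 4 days of 1 cow in the order of the days. Read by the file links, each slide holds arrays of all 3 cows, and the arrays run over the slides by day and then by cow. All arrays of day 0 would then lie on slide 1 and all of day 14 on slide 3. The choice between the readings rested on probes that set the 4 arrays of 1 cow at least 8-fold apart from all others, and it was made before any comparison of days was fitted, but after the conflict and such probes had been looked at, as was the 8-fold limit. The table's cows gave 2, 12 and 6 such probes (cows 1, 2 and 3; 20 in all) and the cows of the file links gave 0. Among the 492 other sets of 4 arrays the mean was 0.0285 probes, but the highest was 6, more than the 2 of cow 1 and as many as the 6 of cow 3. Each array was therefore given the sample of its table column, not the sample GEO links it to, and the file links were kept as an alternative whose counts stand beside the main ones. This check speaks for the cow only, and the day of each array within a cow rests on the table. Slide and cow are 1 factor here, as are day and position on the slide.

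The signals were log2-transformed and each array's 75th percentile over the non-control probes was subtracted. Spots of the same probe were averaged, 1417 control spots were left out, and 31 of 43653 probes were left out for outlier flags. A probe was kept where it was well above background, as called by the scanner software, on at least 3 of the 12 arrays, which left 33539 probes. The 75th percentile of the processed intensity lay between 824 and 1117, and the share of probes well above background between 71.3 and 76.0%, except for the day 2 array of cow 3 with 63.2% (27557 probes). No probe was saturated, and the number of arrays limits the precision of every value.

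Probes were named through the accession in the scanner files and a RefSeq gene table of the ARS-UCD2 assembly, which was used for names only because the file headers give an older build (Btau 3). Of 43653 probes, 20595 were named through their own accession, 1607 through another RefSeq accession, 9849 carried a current symbol and 372 an older one, and 11230 kept the name in the file. The brightest probe of each symbol, by its mean over the 12 arrays, stood for the gene, which gave 12806 genes.

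Days were compared in limma 3.58.1 (R 4.3.3) by a linear model on all 12 arrays with day as factor and cow as block, 6 residual degrees of freedom and 2.33 prior degrees of freedom, with Benjamini-Hochberg adjustment over the 33539 probes at 0.05. Days 2, 7 and 14 were each set against day 0, the later days against each other, and a moderated F-test asked which probes differed among the 4 days. The pairing comes from the design text. As a check, deviations from the day means correlated at a mean of 0.285 over 18 pairs of arrays of the same cow (lowest 0.0235, 15 above 0.1) and at a mean of -0.136 over 36 pairs of different cows. Since the deviations of a day cancel over its 3 cows, the negative mean follows from the positive one and is no separate check. Log2 changes are given with the standard error of the fit, and each rests on 3 cows. Where a probe was not well above background on any of the 3 arrays of a day, the change is given as at least N-fold: the mean of the brighter day against the mean, per array of the dimmer day, of the higher of the probe's own signal and the lowest signal well above background. Such a bound holds for the probe that stands for the gene. Another probe of the gene was well above background on that day for CCL19 (1 of 3 arrays), SLC11A1 (1 of 3), HP (2 of 3) and CCKBR (3 of 3).

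A total of 33 gene lists, each with at least 5 measured members, were fixed before the data were examined, as were the model, the rule for named genes and all alternatives not said to be added. They cover acute inflammation, antimicrobial and acute phase proteins, complement, interferon-stimulated genes, antigen presentation, oxidative stress, cell death, immediate early genes that respond to handling, proliferation, extracellular matrix, proteolysis and remodelling, growth factors, Wnt signalling, stem and side population genes, genes of the oestrogen and of the luteal phase, prostaglandins, cholesterol and lipid synthesis, iodide and thyroid hormone handling, mitochondrial respiration and ribosomal proteins. The others are markers of epithelium, ciliated cells, squamous and basal cells, stromal fibroblasts, smooth muscle and pericytes, endothelium, macrophages, neutrophils, mast cells and eosinophils, T and natural killer cells, B and plasma cells, and red blood cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. For each list the members past 0.05 were counted over all probes and adjusted over the list alone, and the median was also taken with members that have only a bound at that bound. With an estimated correlation no list passed in any comparison, and fry called 6, 9, 0, 0, 0 and 2 lists in the order of comparisons used below.

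Genes are named by rule: for each day against day 0, the 12 largest rises and the 12 largest falls among genes past 0.05 that moved the same way in all 3 cows, and for later days against each other the 5 largest each way (where none passed, the 6 with the smallest p). To these come up to 4 members with the smallest p from every list that camera called and from the lists of acute inflammation, stem and side population, proliferation, oestrogen phase and luteal phase genes, and ESR1, PGR, ABCG2 and PTGS2 in any case. The wording of this rule was fixed beforehand, but its list members and the last 4 genes were at first taken for the comparisons with day 0 alone, and this was corrected to all 6 comparisons after results had been seen. Among genes past 0.05, a second probe had an estimate of the other sign for COL2A1 on day 2 (0.06), CCL19 (-0.35) and PRRX1 (-0.02) on day 7, PDIA2 for day 7 against day 2 (0.10) and STAG3 for day 14 against day 7 (-0.17), none of them past 0.05. Signs also differed between probes of genes that did not pass: PTGS2, RPL8, ABCG2, HMMR, RPLP0, CTNNB1 and ESR1.

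The alternatives left out the cow term, used normexp background correction (offset 50) with quantile normalisation, quantile scaling of the processed intensity, the deposited value table, no filter or a filter on all 12 arrays, an intensity trend, array weights, only the 2 days compared, the slide as a random block, and left out each cow in turn. For lists, the mean of a gene's probes was also tried in place of the brightest. Added after the data were seen were the file links and a run without the day 2 array of cow 3. The model was tested on simulated data for 33539 probes of which 70, 70 and 60 were changed 2-, 4- and 8-fold, with noise that was independent between probes. It recovered 10, 71.4 and 93.3% of probes changed 2-, 4- and 8-fold between day 2 and day 0, with 0.877% of its calls false, and 12.9, 68.6 and 81.7% between day 7 and day 0, with 8.62% false. Between day 14 and day 0 the shares were 20, 78.6 and 85% with 2.44% false, between day 7 and day 2 14.3, 77.1 and 90% with 3.28% false, between day 14 and day 7 11.4, 72.9 and 85% with 5.98% false, and between day 14 and day 2 15.7, 74.3 and 86.7% with 2.54% false. In the simulated comparison of day 7 with day 0, camera called 5 of 5 shifted lists and 0 of 20 unshifted ones. With independent noise this does not test the preset correlation. Tables were read and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.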

Results

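The data were 12 arrays of endometrial RNA, 3 each for day 0, 2, 7 and 14 of a study in which povidone-iodine, an iodine-releasing antiseptic, was given into the uterus of 3 cows. Between 63.2 and 76.0% of probes were well above background on each array, and the number of arrays limits the precision. Every comparison asks how gene expression in the endometrium differed between days in the same 3 cows. As no untreated cow was sampled, a difference between days holds the effects of the antiseptic, of time, of the oestrous cycle and of repeated biopsy together.

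Some probes set the arrays of each cow apart under the sample names of the deposited value table, where each cow filled 1 slide, so that cow and slide cannot be told apart. BLA-DQB, a gene of antigen presentation, had a mean log2 signal of -7.79 on the 4 arrays of cow 2 and 2.75 on the other 8, and BOLA-DQA2 had -7.65 and 1.59. JSP.1, a gene of the same complex, had -5.41 in cow 3 and 4.98 in the others, and TMEM149 had 1.09 in cow 1 and -4.57 in the others. Other probes named for DQ genes went the other way. BOLA-DQB had -0.27 in cow 2 and -8.15 in the others, and the probes of HLA-DQA1 had 0.2 and -0.91 against -8.16 and -8.2. A low signal in cow 2 thus held for single probes and not for DQ genes as a group. The genes of this paragraph were chosen after their values were seen. All results below use the value table's sample names, while the links of the scanner files give other samples for 10 of 12 arrays and other counts, which stand beside each comparison.

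**Figure D1:**
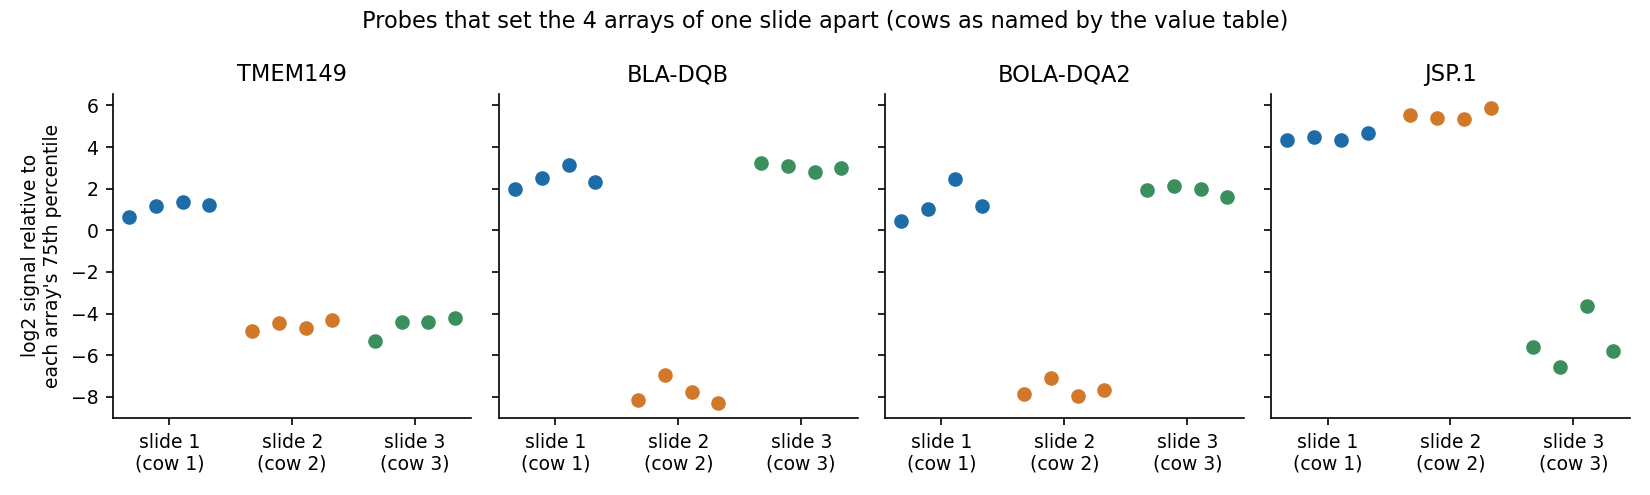
Log2 signal relative to the array's 75th percentile (vertical) of TMEM149, BLA-DQB, BOLA-DQA2 and JSP.1 on the 12 arrays, by slide, which is the cow under the value table. BLA-DQB is low on all 4 arrays of cow 2 (mean -7.79) and JSP.1 on all 4 of cow 3 (mean -5.41).

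The arrays of day 0 and day 7 lay at the ends of the first principal component, which held 27.8% of the variance, with scores from 80.8 to 92.9 on day 0 and from -92.6 to -76.3 on day 7. Day 2 scored from -8.88 to 6.39, and day 14 was spread out, with 30.4, -55.1 and 4.84 for cows 1, 2 and 3. The second component (20.2%) set apart cow 3, whose arrays fill 1 slide. Its arrays scored -10.8, -121.3, -44.6 and -89.3 on days 0, 2, 7 and 14, and those of the other cows from 18.0 to 57.1.

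**Figure D2:**
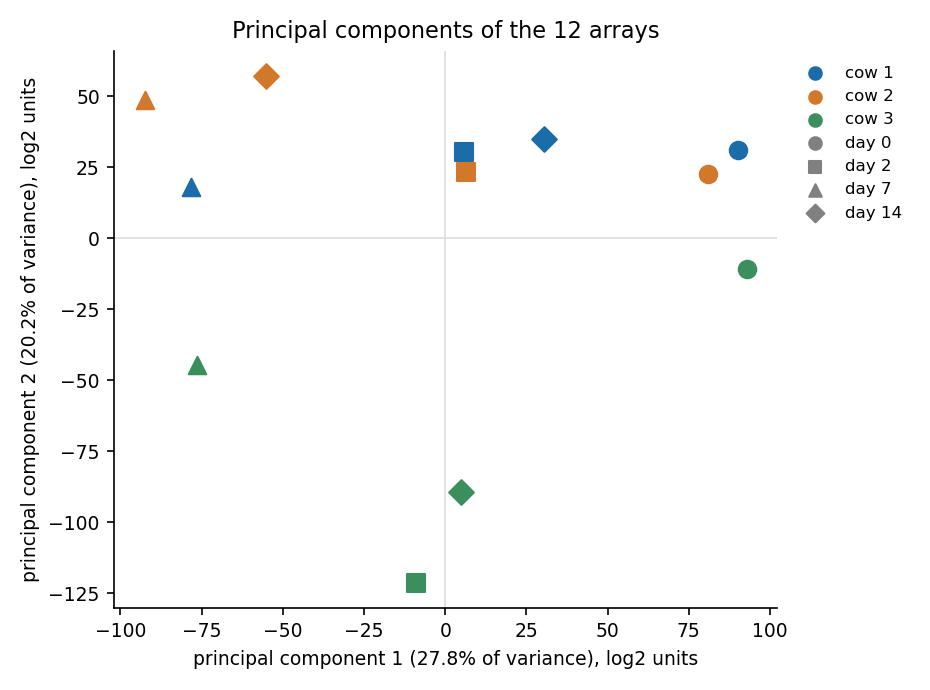
Scores of the 12 arrays on the first (27.8% of the variance) and second (20.2%) principal component, by day and cow. The 3 day 0 arrays and the 3 day 7 arrays lie at opposite ends of the first component.

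On day 2 against day 0, the largest rises included a chemokine gene and beta-defensin genes, each higher in 3 of 3 cows (n = 3). The probe of CCL19, a chemokine that draws T cells and dendritic cells, rose at least 56.4-fold (adjusted p = 0.0116, limma), while the gene's other probe had a log2 change of 0.02. That other probe was well above background on only 1 of 3 arrays of either day, so its change says little. The beta-defensin genes DEFB5 (log2 change 7.38 ± 1.18 SE), DEFB7 (4.51 ± 0.48) and EBD (4.70 ± 0.60) rose, as did DEFB4A (7.16) and DEFB10 (at least 5.61-fold). Defensin genes are close in sequence, and whether their probes bind each other's transcripts was not tested. SLC11A1, a metal transporter of the macrophage phagosome, rose at least 21.2-fold (log2 change 3.19 on the gene's other probe), MMP12, an elastase of macrophages, at least 11.8-fold, and CHI3L1, a chitinase-like glycoprotein, 47.9-fold (log2 change 5.58 ± 0.63). SPP1 (osteopontin, 5.21 ± 1.05), MASP1, a protease of the lectin pathway of complement (5.97 ± 1.21), and C29H11orf86 (at least 27.3-fold) were the other largest rises. The bound of C29H11orf86 is a mean over cows that differed widely. Its log2 signal on day 2 was 0.65, -0.94 and -5.01 in cows 1, 2 and 3. On day 0, DEFB5 and DEFB4A were well above background on 2 of 3 arrays, and DEFB7 and MASP1 on 1 of 3.

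The largest falls on day 2 included some ion channel and collagen genes. KCNH6, a potassium channel subunit, fell at least 28.1-fold and KCNV1 at least 4.13-fold, and SCNN1B, a subunit of the epithelial sodium channel, had a log2 change of -4.83 ± 0.58. The collagen genes COL26A1 (-4.69 ± 0.54), COL2A1 (-4.71 ± 0.89) and COL28A1 (at least 8.24-fold, and -1.85 on the gene's other probe) fell, with COCH (-4.78 ± 0.64), DGKI (-4.28 ± 0.81), CNDP1 (-3.73 ± 0.77), PPP1R1C (at least 19.3-fold), TEX29 (at least 9.49-fold) and BSP3 (at least 5.06-fold). SCNN1B, COCH and CNDP1 were well above background on 1 of 3 arrays of day 2. In all, limma called 846 of 33539 probes (546 higher, 300 lower), which stood for 373 genes (246 higher, 127 lower). Without the cow term 429 probes passed, with no filter 528, with only the 2 days compared 396 and with array weights 5078. Without cow 1 or cow 2 limma called 0 (3284 and 4189 at an unadjusted p under 0.05), and with the scanner files' links it called 0 (336).

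Of the lists, 11 were called on day 2 with the preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05), while fry called 6. Among 28 measured genes of acute inflammation 4 rose over all probes and 11 adjusted over the list alone, among them the chemokine genes CCL2 (3.59 ± 0.44), CCL3 and CXCL8. For the list the median log2 change was 1.05 (adjusted p = 6.97e-06, and 0.496 with an estimated correlation). Of 23 antimicrobial and acute phase genes 8 rose, and 10 rose and 1 fell adjusted over the list alone. The antimicrobial median was 1.40 (adjusted p = 3.64e-05, and 0.153 with an estimated correlation). Of 20 complement genes 6 rose, 11 adjusted over the list alone, with CFP 2.06 and C2 2.19. The complement median was 1.17 (adjusted p = 4.57e-07, and 0.153 with an estimated correlation). Macrophage markers had 1 of 19 past the threshold, CD68 (2.45), and 13 adjusted over the list alone. Their median was 1.28 (adjusted p = 9.79e-07, and 0.529 with an estimated correlation). Of 17 neutrophil markers 1 rose, and 4 rose and 2 fell adjusted over the list alone (median 0.33, adjusted p = 0.237, and 0.597 with an estimated correlation).

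Proliferation genes had the smallest list p on day 2: 4 of 36 rose, and 26 rose and 1 fell adjusted over the list alone. The proliferation median was 1.71 (adjusted p = 7.51e-12, and 0.496 with an estimated correlation). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, rose by a log2 change of 4.47 ± 0.49 and CCNB2, a mitotic cyclin, by 3.13. Of 23 genes of cholesterol and lipid synthesis 2 rose, SQLE (1.56) and MVK (1.06), and 12 adjusted over the list alone. Their median was 0.92 (adjusted p = 2.08e-09, and 0.496 with an estimated correlation). Extracellular matrix genes had 5 of 32 higher, 13 adjusted over the list alone, with FN1 (fibronectin) at 1.74. The matrix median was 0.69 (adjusted p = 2.97e-06, and 0.496 with an estimated correlation). Smooth muscle and pericyte markers had 2 of 20 higher, 7 higher and 1 lower adjusted over the list alone. Their median was 1.03 (adjusted p = 0.000115, and 0.55 with an estimated correlation). DGAT2, an enzyme of triglyceride synthesis, fell by 2.52 on the log2 scale. Of 18 ciliated cell markers 0 passed in limma, with 1 higher and 4 lower adjusted over the list alone. The list median was -1.14 (adjusted p = 0.000421, and 0.57 with an estimated correlation). Immediate early genes, which respond to tissue handling, had 1 of 19 higher, also 1 adjusted over the list alone (median 0.79, adjusted p = 0.027, and 0.55 with an estimated correlation), and oxidative stress genes 3 of 31, with 8 higher and 1 lower adjusted over the list alone (median 0.17, adjusted p = 0.0469, and 0.496 with an estimated correlation). The immediate early call ended without cow 1 (median 0.50, 0.121), the smooth muscle call without cow 3 (median 0.25, 0.134) or its day 2 array (median 0.55, 0.0944). The oxidative stress call ended without cow 1 (0.0923), without cow 2 (0.0594), with quantile scaling (median 0.10, 0.0794) and with normexp and quantile normalisation (median 0.07, 0.0705). The last setting gave medians of 0.55 for acute inflammation, 0.79 for antimicrobial, 0.78 for complement and 1.06 for proliferation genes and -0.60 for ciliated cell markers. Ciliated cell markers had -0.75 without cow 3, and acute inflammation 0.65 without cow 1.

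**Figure D3:**
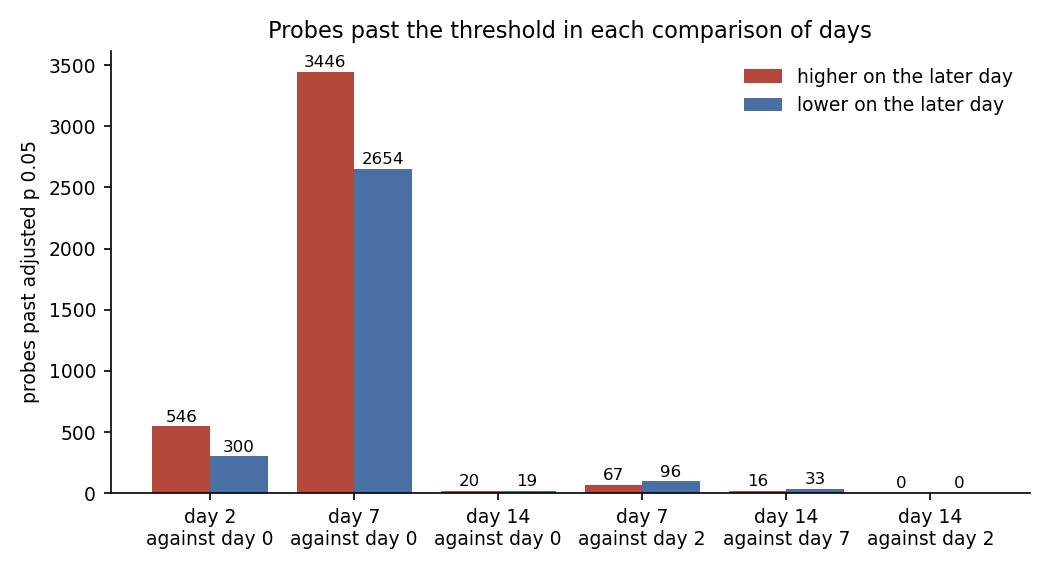
Number of probes past an adjusted p of 0.05 in each comparison of days, higher and lower in the later day, of 33539 tested. Day 7 against day 0 has the largest count (3446 higher and 2654 lower), and day 14 against day 2 has 0.

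On day 7 against day 0, each gene named among the largest rises was higher in 3 of 3 cows (n = 3). REG4, a secreted lectin, rose at least 578-fold (adjusted p = 0.00701, limma), and OXTR, the oxytocin receptor, rose 212-fold (log2 change 7.73 ± 0.95 SE, adjusted p = 0.00363). SERPINA14, the uterine serpin (8.08 ± 1.62), the protease gene MMP7 (7.06 ± 0.94), the ammonia transporter gene RHCG (6.84 ± 0.99), the mucosal scavenger receptor gene DMBT1 (6.26) and MASP1 (7.87 ± 1.21) rose too. The probe of CCL19 rose at least 78.5-fold, with -0.35 on the gene's other probe, which was well above background on only 1 of 3 arrays of either day. The probe of HP, haptoglobin, rose at least 33.6-fold (log2 changes of 2.44, 9.74 and 4.41 in cows 1, 2 and 3), with 4.06 (adjusted p = 0.0941) and 6.42 (0.037) on the gene's other probes. CHI3L1 (5.64), RSPO3, an activator of Wnt signalling (5.47), and the beta-defensin gene EBD completed the largest rises. Receptors of the ovarian steroids rose as well, ESR1 by 1.86 ± 0.35 and PGR by 1.74 ± 0.30. On day 0, MMP7, RSPO3 and TAP were well above background on 2 of 3 arrays and MASP1 on 1 of 3.

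Among the falls on day 7 were CRIPTO, a co-receptor of Nodal (log2 change -6.67 ± 1.56), DGKI (-6.31 ± 0.81), PRODH, which breaks down proline (-6.12 ± 1.29), the collectin gene COLEC11 (-5.45 ± 0.45) and SUSD2, a surface marker of endometrial mesenchymal stem cells (-5.41 ± 1.04). KCNH6 fell at least 35.4-fold, PPP1R1C at least 23.2-fold, TEX29 at least 11.4-fold, WFDC11 at least 9.54-fold and IGF2BP1 at least 8.59-fold, with ENPP3 at -5.02 and PDZK1 at -4.95. COLEC11 was well above background on 1 of 3 arrays of day 7 and ENPP3 on 2 of 3. In all, limma called 6100 of 33539 probes (3446 higher, 2654 lower), which stood for 2468 genes (1399 higher, 1069 lower). Without cow 1 it called 0 (6696 at an unadjusted p under 0.05), without cow 2 it called 213 (104 higher, 109 lower), of which 208 were among the 6100, and with the scanner files' links it called 0 (1770). Only the 2 days compared gave 1879 and array weights 10432. The directions were 3279 higher and 3364 lower with normexp and quantile normalisation, and 3207 and 3059 with quantile scaling.

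On day 7, 14 lists were called with the preset correlation, 9 by fry and 0 with an estimated correlation (2 at an unadjusted p under 0.05). Genes of acute inflammation had 14 of 28 higher, 17 adjusted over the list alone, with the neutrophil-attracting chemokine gene CXCL5 at 4.78 and the adhesion gene SELP at 2.33. Their median log2 change was 1.35 (adjusted p = 0.00067, and 0.668 with an estimated correlation). Antimicrobial genes had 9 of 23 higher, 11 higher and 1 lower adjusted over the list alone, with TAP, a beta-defensin of the airway, at 5.30. The antimicrobial median was 1.40, or 1.36 with members at their bound (adjusted p = 0.00283, and 0.43 with an estimated correlation). Complement genes had 8 of 20 higher, 11 adjusted over the list alone, with CFB at 4.11 and CFI at 3.54. Their median was 1.23 (adjusted p = 0.000316, and 0.43 with an estimated correlation). Macrophage markers had 5 of 19 higher, 10 adjusted over the list alone. The list median was 1.03 (adjusted p = 0.00185, and 0.768 with an estimated correlation). Immediate early genes had 5 of 19 higher, 8 adjusted over the list alone (median 0.82, adjusted p = 0.0105, and 0.768 with an estimated correlation), with FOS at 2.27 and IER3 at 2.97.

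Tissue remodelling genes were among the called lists of day 7. Of 32 extracellular matrix genes 15 rose, 19 adjusted over the list alone, with TNC, a matrix protein of healing tissue, at 4.86 ± 0.61 and FN1 at 2.36. Their median was 1.07 (adjusted p = 2.21e-06, and 0.662 with an estimated correlation). Of 25 proteolysis genes 7 rose and 1 fell, 12 and 3 adjusted over the list alone, with TIMP1, an inhibitor of metalloproteinases, at 2.83 ± 0.27 and the urokinase gene PLAU at 2.64. The list median was 0.97, or 0.74 with members at their bound (adjusted p = 0.00831, and 0.768 with an estimated correlation). Growth factor genes had 8 of 38 higher and 1 lower, 9 and 1 adjusted over the list alone, with INHBA at 4.33, HGF at 2.61 and VEGFA at 1.35. Their median was 0.78 (adjusted p = 0.0163, and 0.768 with an estimated correlation). Smooth muscle and pericyte markers had 9 of 20 higher, 11 higher and 1 lower adjusted over the list alone (median 1.28, adjusted p = 0.00185, and 0.768 with an estimated correlation), and stromal fibroblast markers 3 of 21 higher and 1 lower, 3 and 1 adjusted over the list alone (median 0.62, adjusted p = 0.0163, and 0.768 with an estimated correlation).

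Oestrogen phase genes had 5 of 15 higher on day 7, 8 higher and 1 lower adjusted over the list alone (median 1.62, adjusted p = 0.0481, and 0.668 with an estimated correlation), and luteal phase genes 6 of 24 higher and 2 lower, 8 and 4 adjusted over the list alone (median 0.50, adjusted p = 0.545). Proliferation genes went both ways, with 4 of 36 higher and 2 lower, 5 and 2 adjusted over the list alone (median 0.93, adjusted p = 0.00945, and 0.849 with an estimated correlation): RRM2 rose by 3.79 while the mitotic cyclin gene CCNB1 fell by 2.37 on the log2 scale. Cholesterol synthesis genes had 7 of 23 higher, 8 adjusted over the list alone (median 0.52, adjusted p = 0.00831, and 0.768 with an estimated correlation), and ciliated cell markers 1 of 18 higher and 2 lower, also 1 and 2 adjusted over the list alone. The ciliated cell median was -1.02 (adjusted p = 0.00416, and 0.768 with an estimated correlation). DGAT2 fell by 3.04 on the log2 scale. Without cow 1 the calls of oestrogen phase (median 0.89, adjusted p = 0.0881), growth factor (0.0815), immediate early (0.0815) and stromal genes (0.063) ended. Without cow 3 the calls ended of oestrogen phase (0.159), proliferation (median 0.44, 0.173) and cholesterol genes (0.122). Without the cow term those of oestrogen phase genes and ciliated cell markers ended (0.0717 each). With normexp and quantile normalisation the medians were 0.76 for acute inflammation, 0.74 for antimicrobial, 0.79 for complement, 0.49 for proteolysis, 0.48 for growth factor, 0.40 for stromal, 0.71 for oestrogen phase and 0.49 for proliferation genes and -0.63 for ciliated cell markers. Without cow 1 they were 0.88 for acute inflammation and 2.29 for antimicrobial genes, and without cow 2 0.62 for proteolysis genes. Without cow 3 they were 1.28 for immediate early genes and -0.68 for ciliated cell markers.

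**Figure D4:**
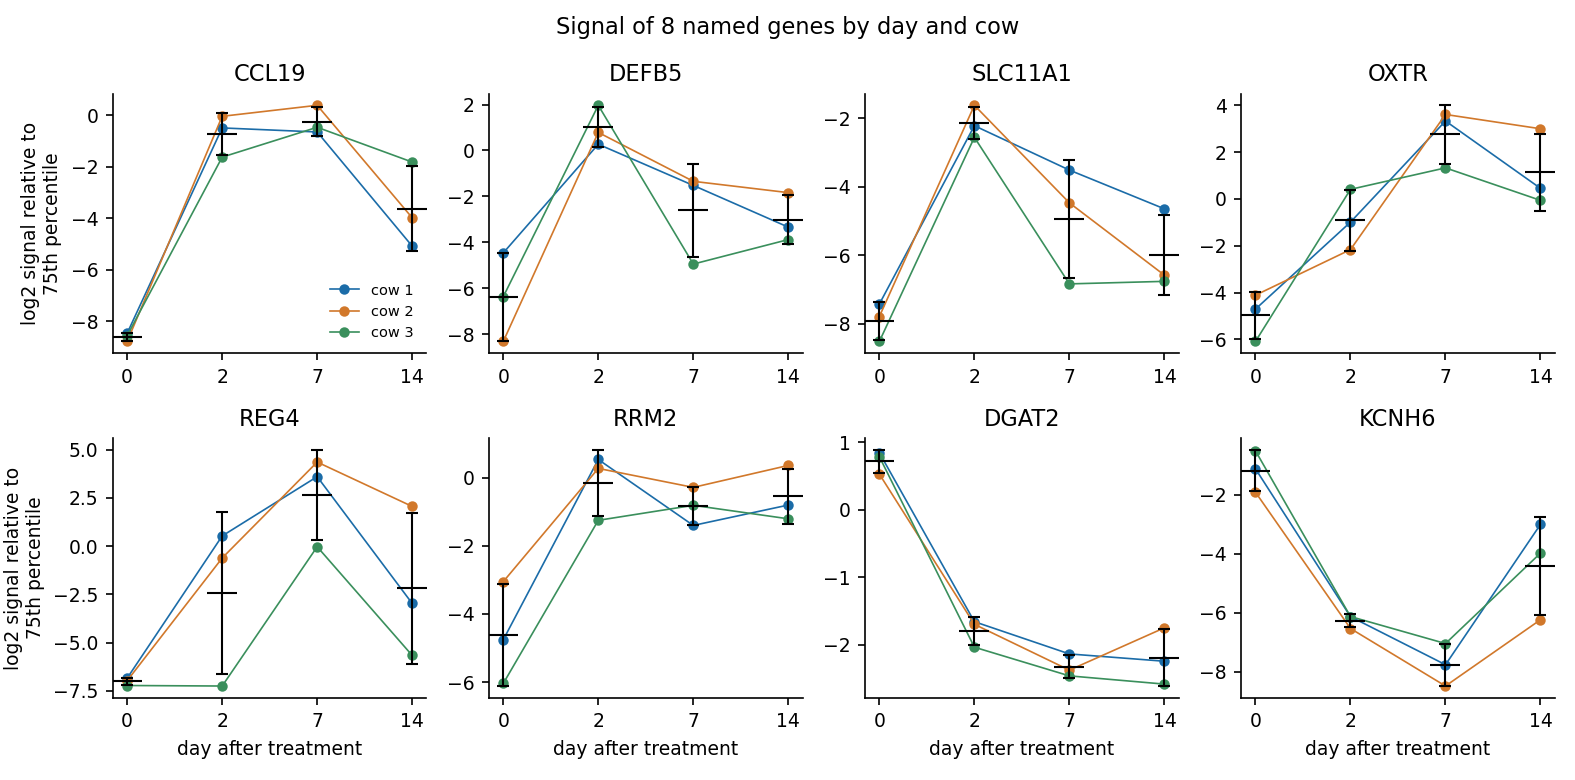
Log2 signal relative to the array's 75th percentile (vertical) of 8 genes on each day, a point per cow, with the mean and SD of 3 cows as black bars. OXTR rose by 7.73 on the log2 scale from day 0 to day 7, and DGAT2 fell by 2.52, 3.04 and 2.91 on days 2, 7 and 14.

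On day 14 against day 0, 13 genes passed the threshold and moved the same way in 3 of 3 cows (n = 3). RRM2 rose by 4.07 ± 0.49 SE on the log2 scale (adjusted p = 0.044, limma), GPNMB, a glycoprotein of macrophages, by 3.25 ± 0.42, SLC1A5, a glutamine transporter, by 2.17 ± 0.23, B3GNT8 by 1.96, SPIC, a transcription factor of macrophages, by 1.80, and GMIP by 1.25. DGAT2 (-2.91 ± 0.21, adjusted p = 0.0122), PDZK1IP1 (-3.10 ± 0.28), PMFBP1 (at least 2.59-fold), ARHGAP44 (-1.92), the lysosomal phosphatase gene ACP2 (-1.58), TMEM35A (-1.57) and TMEM192 (-1.35) fell. OXTR, at a log2 change of 6.10 (adjusted p = 0.0545), ESR1 at 0.99 (0.172) and PGR at 0.49 (0.375) did not pass. In all, limma called 39 of 33539 probes (20 higher, 19 lower; 6890 at an unadjusted p under 0.05). Without cow 1, 2 or 3 it called 0 each time (3861, 3553 and 7966 at an unadjusted p under 0.05), and with the scanner files' links it called 237. The count was 817 with normexp and quantile normalisation (347 higher, 470 lower), 371 with the slide as random block, 346 with array weights, 309 with an intensity trend, 291 with a filter on all 12 arrays, 104 with quantile scaling, 4 with no filter and 0 in limma with only the 2 days compared (5033 at an unadjusted p under 0.05).

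Of the lists, 8 were called on day 14, 0 by fry (8 at an unadjusted p under 0.05) and 0 with an estimated correlation (2), and members past the threshold over all probes were found in 1 of them. That was proliferation, with 1 of 36 higher, and 26 higher and 1 lower adjusted over the list alone. Their median log2 change was 1.85 (adjusted p = 6.84e-13, and 0.786 with an estimated correlation). Adjusted over the list alone, 11 of 32 extracellular matrix genes (median 0.67, adjusted p = 2.55e-08, and 0.683 with an estimated correlation), 5 of 19 immediate early genes (median 0.54, adjusted p = 0.0037, and 0.786), 5 of 23 antimicrobial genes (median 0.74, or 0.68 with members at their bound, adjusted p = 0.00824, and 0.683), 1 of 28 genes of acute inflammation (median 0.65, or 0.57 with members at their bound, adjusted p = 0.00824, and 0.786) and 1 of 21 stromal markers (median 0.53, adjusted p = 0.00824, and 0.786) were higher, the last p each being with an estimated correlation. Smooth muscle markers (median 0.82, adjusted p = 0.00295, and 0.786 with an estimated correlation) and 28 ribosomal protein genes (median 0.30, adjusted p = 0.000103, and 0.786 with an estimated correlation) had 0 members past the threshold in limma over all probes or adjusted over the list alone, and the ribosomal median was 0.05 with quantile scaling and -0.01 with normexp and quantile normalisation, with neither call kept. Without cow 1 the calls of acute inflammation (adjusted p = 0.0937), immediate early (median 0.36, 0.0901) and stromal genes (0.0631) ended, without cow 2 those of acute inflammation and ribosomal genes (0.0661 each, ribosomal median 0.14), and without cow 3 those of antimicrobial (0.0513) and smooth muscle genes (median 0.28, 0.052). The smooth muscle call also ended without the cow term (0.0513), and with normexp and quantile normalisation those of acute inflammation (median 0.33, 0.0526) and antimicrobial genes (median 0.23, 0.0883), while proliferation had 1.17. The antimicrobial median was 1.40 without cow 2 and the immediate early median 0.85 without cow 3.

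**Figure D5:**
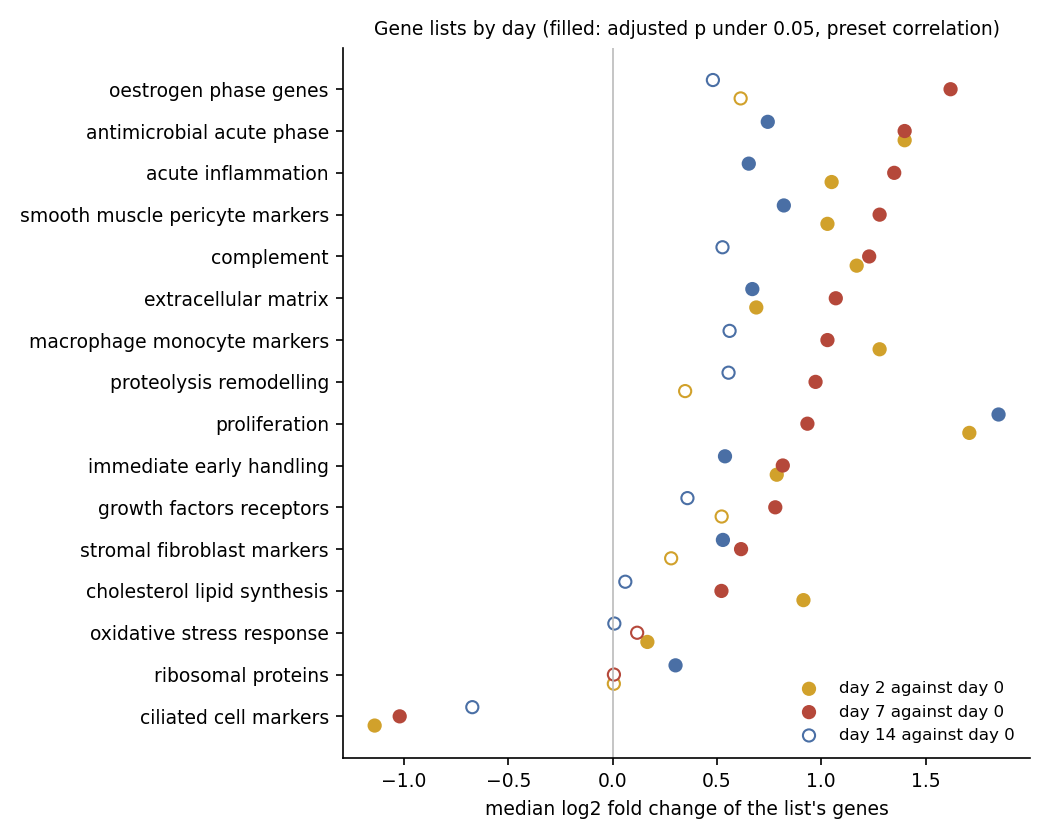
Median log2 change of the measured members of 16 gene lists on days 2, 7 and 14 against day 0, filled where the adjusted p with the preset correlation was under 0.05. Proliferation genes have medians of 1.71, 0.93 and 1.85, and no list was called with an estimated correlation.

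Between day 7 and day 2, the genes past the threshold named here moved the same way in 3 of 3 cows (n = 3). NPPC, C-type natriuretic peptide, rose at least 134-fold (adjusted p = 0.0371, limma), ADAMTS18 at least 17.5-fold, the potassium channel genes KCNJ15 by a log2 change of 4.32 and KCNJ16 at least 4.78-fold, and CDKN2B, an inhibitor of the cell cycle, by 3.77 ± 0.54 SE. WFDC11 fell at least 44.9-fold, CES4A at least 33.5-fold, COLEC11 (-4.02 ± 0.45) and PDIA2 (-4.01) fell, and the probe of CCKBR fell at least 20.5-fold while the gene's other probe had a log2 change of -0.29 (adjusted p = 0.599). COLEC11 and PDIA2 were well above background on 1 of 3 arrays of day 7 and KCNJ15 on 2 of 3 of day 2. Proliferation genes had 2 of 36 lower, TK1 (-1.52 ± 0.17) and CCNB1 (-2.59 ± 0.36), and 3 adjusted over the list alone. The proliferation median was -0.85 (adjusted p = 2.43e-05, and 0.925 with an estimated correlation). Wnt signalling genes had 0 of 28 past the threshold over all probes, 7 higher and 1 lower adjusted over the list alone (median 0.76, adjusted p = 0.0363, and 0.899 with an estimated correlation), while cholesterol synthesis (median -0.35, adjusted p = 0.0363) and mitochondrial respiration genes (median -0.21, adjusted p = 0.00439) had 0 either way, each with an adjusted p = 0.925 with an estimated correlation. In all, limma called 163 of 33539 probes (67 higher, 96 lower), and 4 lists, against 0 by fry (2 at an unadjusted p under 0.05) and 0 with an estimated correlation (1). Without cow 1 or 2 limma called 0 probes (2781 and 2823 at an unadjusted p under 0.05), without cow 3 it called 2132, with the scanner files' links 0 (1398), and the lists numbered 2 without cow 1, with 0 of the 4 among them (medians -0.25 for proliferation, -0.12 for cholesterol and -0.10 for mitochondrial genes). They numbered 12 without cow 3 (-1.61 for proliferation, -0.61 for cholesterol genes), or 10 without the day 2 array of cow 3 (-1.32 and -0.60). The proliferation median was -0.57 with normexp and quantile normalisation. The probes numbered 441 with normexp and quantile normalisation, 411 with the slide as random block, 355 with an intensity trend, 266 with a filter on all 12 arrays, 10147 with array weights, 51 with no filter and 0 in limma with only the 2 days compared (4801 at an unadjusted p under 0.05).

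Between day 14 and day 7, the largest falls, each in 3 of 3 cows (n = 3), included that of a mucin gene. MUC13, a membrane mucin, had a log2 change of -6.82 ± 0.78 SE (adjusted p = 0.0357, limma), TAP of -4.37 ± 0.51, CDKN2B of -4.04 ± 0.54 and MPP6 of -2.55, and KCNJ16 fell at least 6.54-fold. On day 14, MUC13 and MPP6 were well above background on 1 of 3 arrays and TAP on 2 of 3. ERP27, a protein of the endoplasmic reticulum, rose by 3.17 ± 0.30, PACSIN1 by 2.71, RGS11 by 2.58, SAT2 by 1.54 and STAG3 by 1.52. Adjusted over the list alone, 10 of 20 complement genes were lower and 1 higher (median -1.26, adjusted p = 1.71e-05, and 0.505 with an estimated correlation), 9 of 25 proteolysis genes lower and 1 higher (median -0.87, adjusted p = 0.00635, and 0.722), 4 of 23 cholesterol genes lower (median -0.59, adjusted p = 0.000765, and 0.722), 1 of 28 genes of acute inflammation lower (median -0.76, adjusted p = 0.0125, and 0.722) and 4 of 11 red blood cell genes higher (median 0.26, adjusted p = 0.0256, and 0.722), the last p each being with an estimated correlation. In all, limma called 49 of 33539 probes (16 higher, 33 lower), against 18 without the cow term, and 11 lists, against 0 by fry (7 at an unadjusted p under 0.05) and 0 with an estimated correlation (1). Without cow 1 or 2 it called 0 probes (2351 and 3437 at an unadjusted p under 0.05), without cow 3 142 (88 higher, 54 lower), of which 18 were among the 49, and with the scanner files' links 215. The cholesterol call ended without cow 2 (median -0.32, adjusted p = 0.0859) and the red blood cell call without cow 3 (median 0.50, 0.0663) and with quantile scaling (0.053). Without cow 1 the medians were -0.80 for complement, -0.54 for proteolysis and 0.85 for red blood cell genes. With normexp and quantile normalisation they were -0.72 for complement, -0.39 for acute inflammation and 0.10 for red blood cell genes. It called 467 with normexp and quantile normalisation, 345 with an intensity trend, 305 with the slide as random block, 276 with a filter on all 12 arrays, 9411 with array weights, 32 with quantile scaling, 7 with no filter and 0 with only the 2 days compared (5239 at an unadjusted p under 0.05).

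Between day 14 and day 2, limma called 0 of 33539 probes (4226 at an unadjusted p under 0.05, smallest adjusted p = 0.0698; n = 3). Among the genes with the smallest p were 2 rises, MDK, a heparin-binding growth factor, with a log2 change of 2.60 and COL26A1 with 5.39, both at an adjusted p of 0.0698. The other genes that the naming rule gives here, falls among them, are not listed, and none passed. The count was 13 without the cow term, 0 without cow 1 or 2 (1998 and 1562 at an unadjusted p under 0.05), 1 without cow 3, 194 with the scanner files' links, 42 with the slide as random block, 12 with normexp and quantile normalisation, 12 with an intensity trend, 6 with a filter on all 12 arrays and 15532 with array weights. Lists called numbered 13, against 2 by fry and 0 with an estimated correlation (6 at an unadjusted p under 0.05). Adjusted over the list alone, 13 of 23 cholesterol genes were lower (median -0.86, adjusted p = 2.01e-12, and 0.261 with an estimated correlation), as were 5 of 20 complement genes (median -1.23, adjusted p = 5.59e-08, and 0.172), 7 of 23 antimicrobial genes (median -0.74, adjusted p = 0.00904, and 0.186) and 5 of 24 luteal phase genes (median -0.58, adjusted p = 0.00221, and 0.172), the last p each being with an estimated correlation. The luteal call ended without cow 3 (adjusted p = 0.0679), and the luteal median was -0.32 without cow 1. The antimicrobial median was -0.37, -0.21 and -1.39 without cow 1, 2 and 3, -0.48 with normexp and quantile normalisation and -0.46 with the mean of a gene's probes.

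Over all 4 days, limma's moderated F-test called 2623 of 33539 probes, which stood for 1062 genes, against 1565 without the cow term, 1443 with no filter and 20619 with array weights. Without cow 1 or 2 it called 0 (4151 and 4566 at an unadjusted p under 0.05), and with the scanner files' links 123.

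Stem cell and side population genes, a list that bears on the dye-excluding cells of the endometrium, were not called in any comparison. On day 2, 1 of 27 rose and 1 fell, 4 and 2 adjusted over the list alone (median log2 change 0.22, adjusted p = 0.222): CD44, a receptor for hyaluronan, rose by 2.63 ± 0.26 and LGR5, a receptor for R-spondins, fell by 1.89 on the log2 scale, well above background on 1 of 3 arrays of day 2. On day 7, 3 rose and 1 fell, 9 and 3 adjusted over the list alone (median 0.25, adjusted p = 0.633), with CD44 at 3.04, ENG at 1.00 and MCAM at 0.79. In the other direction, SUSD2, described above as a surface marker of endometrial mesenchymal stem cells, was among the largest falls of that day. ABCG2, the transporter that exports the dye, had log2 changes of -0.43, -0.32 and -0.37 on days 2, 7 and 14 (adjusted p = 0.416, 0.446 and 0.483), and PTGS2, a cyclooxygenase, 0.27, -0.17 and -1.62 (0.896, 0.916 and 0.359). The cows differed for PTGS2: from day 0 to day 2 its log2 signal rose in cows 1 and 2 but fell in cow 3 (-2.12 to -3.67).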

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

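The tests of array position, cycle stage, the day 2 array of cow 3, neutrophils, epithelial share and the sample names of the arrays were chosen only after the results they bear on were seen; the counts over other splits of the samples were planned before those splits were run. The test of epithelial share was replaced after the median of the epithelial markers (-0.17) had first been read as arguing against a smaller share and then as leaving it open, and the test of cycle stage was then moved from 4 genes of the cycle lists to the whole lists. A pair of results stood out because the change from day 0 differed between later days when the difference itself was tested. It differed for 163 probes between day 7 and day 2, with NPPC at least 134-fold higher on day 7, and for 49 probes between day 14 and day 7, with MUC13 at a log2 change of -6.82.

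Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split gave 846 (day 2 against day 0), 6100 (day 7 against day 0), 39 (day 14 against day 0), 163 (day 7 against day 2) and 49 probes (day 14 against day 7), against 0, 0, 0, 1 and 0 for the highest other split, so that 1 of 10 gave as many in each. For day 14 against day 2 the real split gave 0 probes in limma (4226 at an unadjusted p under 0.05), the highest other 4, and 10 of 10 gave as many. Of the 10 splits 4, the real one among them, part each cow's pair of arrays, while the others leave a pair together. The highest other among these was 0, 0, 0, 1, 0 and 0. For the F-test over all 4 days, 100 regroupings of the days within cows were drawn from 576, the real one included. Of these, 1 gave as many as the real 2623 probes, and the highest other gave 132. This argues against chance, which a draw of this size cannot exclude. Without cow 1 or cow 2 the F-test called 0 (4151 and 4566 at an unadjusted p under 0.05).

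List counts with the preset correlation were as high in other splits. The real counts were 11, 14, 8, 4, 11 and 13 lists (day 2, 7 and 14 against day 0, day 7 against day 2, day 14 against day 7 and day 14 against day 2), the highest others 15, 15, 14, 16, 14 and 15, and 5, 2, 6, 10, 4 and 2 of the 10 splits gave as many as the real one. Shared variation among the genes of a list may account for calls of this kind, as 0 lists were called with an estimated correlation in each comparison.

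The first pattern weighed is the 6100 probes of day 7 against day 0, whose arrays sat at position 3 and position 1 of each slide. The largest difference of 8 spike-in probes, which each sample got in the same amount, was 0.30 on the log2 scale. This is 0.262 of the median size of the called probes (1.15), which were picked as changed. As far as 8 probes can show, this argues against array position as the whole cause. They cannot show an effect of position that differs between probes. Stage of the oestrous cycle stays open: 5 of 15 oestrogen phase genes and 8 of 24 luteal phase genes (6 higher, 2 lower) passed the threshold, 33.3% of the 39 (binomial limits 19.1 to 50.2%) against 19.3% of all genes, and with no untreated cow the cycle and the treatment cannot be told apart. The effect of povidone-iodine itself, time and repeated biopsy are untested for the same reason.

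The second pattern is the higher level of antimicrobial and inflammatory genes on day 2, with 12 of 51 members called and a median log2 change of 4.05 among these. Without the weaker day 2 array of cow 3 the called members kept a median of 0.967 of their change (0.762 to 1.19). These members were picked by a fit that holds that array and favours like changes in all 3 cows. A ratio near 1 was thus largely fixed by the choice, and that array as the cause stays open. Of the 846 probes called on day 2 against day 0, 364 were also called without that array, with fewer arrays in the fit. A smaller share of epithelial cells alone would raise the markers of all other cell types alike. Of 8 such lists, macrophage markers had the highest median (1.28) and mast cell and eosinophil markers the lowest (-0.47). Their difference was 1.75 (95% bootstrap limits 1.15 to 2.52, which take the genes as independent) and at least 1.55 in each of the 3 cows. Picked as the extremes, this pair differs by choice, which is no test. Endothelial markers had 0.02 (-0.228 to 0.475), T cell markers -0.16 (-0.425 to -0.0971) and B cell markers -0.33, which argues against a smaller share alone. Smooth muscle and pericyte (1.03, and 2.81 in cow 3) and stromal markers (0.28) rose, and ciliated cell markers were lower (-1.14). A smaller share joined to other changes therefore stays open, as does a change in macrophages. More neutrophils stay open: 15 neutrophil markers of no other list had a median of 0.33 (0.332, limits -0.0965 to 1.36), below 2.03, which is 0.5 times the median of the called members, but 1 marker passed the threshold, S100A12 at 3.78. Treatment as the biological explanation is untested, as no cow went untreated.

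The third pattern is the conflict over which array is which sample. The scanner files may be linked to the wrong samples: 20 probes set the 4 arrays of a cow of the value table at least 8-fold apart from the others, 2, 12 and 6 for cows 1, 2 and 3. That the value table names the wrong cows is argued against by 0 such probes for the cows of the file links. A set of 4 arrays of differing cows, the 3 of day 7 among them, also reached 6 probes, so the 2 probes of cow 1 and the 6 of cow 3 carry little weight on their own, and as each cow filled 1 slide, cow and slide cannot be told apart. No test was aimed at the order of the days within a cow. The table's days gave 2623 probes in the F-test, against at most 132 in the other drawn regroupings of the days within cows. This speaks for the table's sets of like arrays across cows, but not for which set is which day. The names of the days rest on the value table alone, and day and position on the slide are 1 factor.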

How the results depend on the processing

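The file links and the run without the day 2 array of cow 3 were chosen only after the data were seen. The number of arrays and the share of probes well above background (63.2 to 76.0%) limit what can be seen, and where no reason is given the cause was not tested. Counts below are of probes, for day 2, 7 and 14 against day 0, day 7 against day 2, day 14 against day 7, day 14 against day 2 and any day, or those named.

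Each cow left out gave 0 to 841, 0 to 6229, 0 to 0, 0 to 2132, 0 to 142, 0 to 1 and 0 to 3289, with fewer arrays in the fit. The zeros are limma's without cow 1 (3284, 6696, 3861, 2781, 2351, 1998 and 4151 at an unadjusted p under 0.05), without cow 2 (4189, 3553, 2823, 3437, 1562 and 4566, with 213 called for day 7 against day 0) and, for day 14 against day 0, without cow 3 (7966). Without the cow term the count was 429 for day 2 against day 0, 18 for day 14 against day 7, 13 for day 14 against day 2 and 1565 for any day. The arrays of only the 2 days compared gave 396 and 1879 for days 2 and 7 against day 0, and 0 in limma for day 14 against day 0, day 7 against day 2 and day 14 against day 7 (5033, 4801 and 5239 at an unadjusted p under 0.05), with fewer arrays to estimate the spread.

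For day 14 against day 0, day 7 against day 2, day 14 against day 7 and day 14 against day 2, normexp with quantile normalisation gave 817, 441, 467 and 12, a filter on all 12 arrays 291, 266, 276 and 6, an intensity trend 309, 355, 345 and 12, and the slide as random block 371, 411, 305 and 42. Quantile scaling gave 104 for day 14 against day 0 and 32 for day 14 against day 7. No filter gave 528 for day 2 and 4 for day 14 against day 0, 51 for day 7 against day 2, 7 for day 14 against day 7 and 1443 for any day. Array weights, whose fit stopped before it converged and which ran from 0.184 to 11.2, gave 5078, 10432, 346, 10147, 9411, 15532 and 20619. The slide as a fixed block beside the cow was not run, since slide and cow are the same factor. The file links gave 0, 0, 237, 0, 215, 194 and 123 (336, 1770 and 1398 at an unadjusted p under 0.05 for the zeros). The value table and the run without the day 2 array of cow 3 moved no count of probes beyond 1.5 times. The probes called were not all the same without that array. For day 2 against day 0 it gave 566, with 364 of the main 846 among them. For day 7 against day 2 it gave 135, with 67 of the main 163 among them.

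Of 410 values of named genes, 0 turned direction across the threshold under the settings other than the file links. This was in part fixed by the rules. The largest changes were named only if alike in all 3 cows, so leaving out a cow could not turn them. A turn counted only where the main or the other fit passed, and settings such as an intensity trend leave the log2 change as it was. The count therefore says little on how firm the directions are. Of the 410 values, 169 were past the threshold in the main fit. Without cow 1, all 169 of these were no longer past it, without cow 2 154 and without cow 3 46. Only the 2 days compared lost 89, no cow term 47 and no filter 44, while array weights added 177. Under the file links 90 of 169 values past the threshold turned direction and 0 were still past it.

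Lists called were 0 in each comparison with an estimated correlation (2, 2, 2, 1, 1 and 6 at an unadjusted p under 0.05) and 6, 9, 0, 0, 0 and 2 with fry. Normexp with quantile normalisation gave 5 for day 14 against day 0 and 7 for day 7 against day 2, and quantile scaling 7 for day 14 against day 7. Each cow left out gave 9 to 14, 10 to 15, 6 to 8, 2 to 12, 9 to 12 and 12 to 14, and without the day 2 array of cow 3 day 7 against day 2 gave 10. The ribosomal median of day 14 against day 0 was -0.00613 with normexp and quantile normalisation (0.30 in the main result), and the median of ciliated cell markers of day 14 against day 2 ran from -0.0745 (without cow 2) to 0.854 (without cow 3), against 0.35 in the main result.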

Other observations

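The genes in this part that the naming rule does not give, and the choice of lists to describe, were picked after their values were seen. On day 7 against day 0, endothelial markers had 5 of 21 higher and 1 lower, also 5 and 1 adjusted over the list alone (median log2 change 0.08, adjusted p = 0.511): VWF, the clotting factor carrier of vessel walls, rose by 2.04 ± 0.45 SE, LYVE1 of lymphatic vessels by 1.72 ± 0.34 and PECAM1 by 1.18 ± 0.23, while SOX17 fell by 1.91 on the log2 scale. Of 32 interferon-stimulated genes 2 rose and 4 fell, also 2 and 4 adjusted over the list alone (median 0.04, adjusted p = 0.555), among them GBP4 (-3.46 ± 0.53), HERC5 (-1.60 ± 0.29) and STAT2 (0.79 ± 0.13). Of 19 prostaglandin genes 1 rose and 3 fell, 2 and 3 adjusted over the list alone (median -0.17, adjusted p = 0.837): HPGD, which breaks prostaglandins down, fell by 3.08, PLA2G4A, which frees their precursor, fell by 1.35, and the transporter gene SLCO2A1 rose by 1.56. Of 11 genes of iodide and thyroid hormone handling 2 rose and 1 fell, 4 and 1 adjusted over the list alone (median -0.17, or 0.0 with members at their bound, mean 0.77, adjusted p = 0.781): the anion channel gene CFTR rose by 3.29 ± 0.75, TTR, a carrier of thyroid hormone, by 3.36 ± 0.89, and the receptor gene THRA fell by 0.86.

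Lymphocyte genes were higher on day 14 than on day 2 as lists. Adjusted over the list alone, 6 of 21 T and natural killer cell markers (median log2 change 0.72, adjusted p = 1.35e-05, and 0.185 with an estimated correlation) and 5 of 11 B and plasma cell markers (median 0.85, adjusted p = 0.00515, 0.391 with an estimated correlation, and 0.0828 without cow 3) passed, and 0 over all probes in limma, where 4226 probes had an unadjusted p under 0.05. The T cell median was 0.37 without cow 1 and 0.36 with normexp and quantile normalisation, which gave 0.34 for B and plasma cells. CD3E, of the T cell receptor complex, had a log2 change of 1.45 ± 0.21 (adjusted p = 0.0896) and CD5 1.82 ± 0.34 (0.15). Hemoglobin genes between day 14 and day 7 had values of 4.49 for HBB (adjusted p = 0.0777) and 2.56 for HBA (0.0666).

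The other lists called between later days had 0 members past the threshold over all probes. For day 14 against day 7 these were ribosomal proteins (median 0.27, adjusted p = 3.83e-05), proliferation (0.95, 7.72e-07), macrophage markers (-0.58, 0.0209), mitochondrial respiration (0.15, 0.0232), T and natural killer cell markers (0.23, 0.0256) and ciliated cell markers (0.56, 0.0256), each with 0 adjusted over the list alone and an adjusted p = 0.722 with an estimated correlation. Of the 6 lists called higher in that comparison, 2 kept the call with quantile scaling and 4 with normexp and quantile normalisation: the ribosomal (medians 0.06 and 0.06, adjusted p = 0.0913 and 0.0912) and T cell calls (medians 0.17 and 0.09, 0.0615 and 0.109) ended with each, and the ciliated call (0.0615) with quantile scaling. The ciliated and T cell calls also ended without the cow term (0.174 and 0.16). So did the ciliated (median 0.23, 0.154), macrophage (0.154) and mitochondrial calls (median 0.03, 0.864) without cow 1, the ciliated (median 0.14, 0.201), ribosomal (median 0.14, 0.0859) and T cell calls (0.0972) without cow 2, and the T cell call without cow 3 (0.363). The T cell median was 0.40 without cow 1 and 0.14 with the mean of a gene's probes, the mitochondrial 0.25 without cow 2 and 0.24 without cow 3, and the ciliated 0.97 without cow 3. For day 14 against day 2 they were macrophage markers (median -0.69, adjusted p = 5.43e-05, and 0.61 with an estimated correlation), ribosomal proteins (0.25, 9.61e-05, and 0.701), oxidative stress (-0.24, 0.00221, and 0.186), Wnt signalling (0.38, 0.00904, and 0.185), mast cell and eosinophil markers (0.71, or 0.58 with members at their bound, 0.0157, and 0.364), acute inflammation (-0.22, 0.0157, and 0.61) and ciliated cell markers (0.35, 0.024, and 0.753). The ciliated median turned to -0.07 without cow 2 (adjusted p = 0.881), was 0.85 without cow 3, and the call ended without the cow term (0.204) and with quantile scaling (0.092). The ribosomal call ended with quantile scaling (median 0.07, 0.294), with normexp and quantile normalisation (median 0.04, 0.293) and without cow 2 (median 0.09, 0.393). The Wnt call ended without cow 2 (median 0.25, 0.0652), and the macrophage (median -0.30, 0.0706) and acute inflammation calls (0.053) without cow 3. The mast cell and eosinophil call ended without cow 1 (0.104), with normexp and quantile normalisation (median 0.32, 0.06) and with the mean of a gene's probes (0.0573). Medians were -1.12 for macrophage markers without cow 2, 0.62 for Wnt genes without cow 1, and 1.49 for mast cell markers and -0.39 for oxidative stress genes without cow 3. Without the day 2 array of cow 3 they were -0.44 for macrophage markers, -0.47 for acute inflammation, 1.54 for mast cell markers and 0.57 for Wnt genes.

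Lists of antigen presentation, cell death, squamous and basal cells and epithelium were called in no comparison. On day 7 against day 0 their medians were 0.22 over 20 genes (adjusted p = 0.511), 0.04 over 28 (0.844), -0.22 over 16 (0.747) and -0.15 over 27 (0.626), with 2, 3, 2 and 1 members higher and 0, 0, 1 and 0 lower.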
